A study of Rattus norvegicus with 40 samples.

How the data were processed

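Hippocampal RNA (100 ng per sample) from rats killed at postnatal day 55 was measured on Affymetrix whole-transcript rat gene arrays, 1 array per sample and 4 per group, in 10 groups of sex, dose and exposure window. The values were log2 signals as deposited, made by the authors with RMA, which corrects background, equalises the distributions of arrays and summarises probes into probe sets; RMA and Partek are named per the submitters' processing notes, without versions or settings. The values ran from 2.07 to 13.93, array medians lay between 6.96 and 7.06, and the values were used as deposited.

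Samples were grouped by their labels alone. Of 29214 probe sets, 15310 carried 1 gene symbol, 323 were shared by several symbols and 13581 carried none. All 29214 were tested for differences, and tests on gene lists used 14506 genes, each represented by its probe set of highest mean. A limma model (limma 3.58.1 in R 4.3.3, statmod 1.5.0) with a mean for each of the 10 groups was fitted to all 40 arrays, with empirical Bayes moderation and a trend of variance on mean signal. It gave 21 contrasts: 8 exposures against controls of the same sex label, 4 of dose, 4 of exposure window, 1 of sex in controls and 4 interactions of sex with lead. The p-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05. Gene lists (36 lists of 564 genes, 483 of them measured) covered neuronal, glial and vascular cell types, neighbouring tissues, signalling, stress and metal handling, and were fixed before the data were examined, as were the contrasts, the naming rule and most other settings tried. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within each contrast, and again with the correlation estimated for each list. Counts "adjusted over the list alone" used the list's own genes.

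Genes were named by rule. Each gene was represented by its probe set of highest mean. In each exposure contrast the rule took up to 8 higher and 8 lower called genes of largest difference whose 4 values in one group did not overlap the 4 in the other, and in other contrasts 3 and 3. Where none passed, it took the 3 of smallest p. Up to 4 members of smallest p were taken from each list that passed, and genes with a record in lead toxicology were taken as well, of which part is not reported here. Mx2, Fkbp5, Sgk1, the Mup probe sets, Eif2s3 and the liver genes were named after their values were seen, as were other genes singled out outside this rule.

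Simulated data covered all 40 arrays, with probe sets shifted in the males exposed perinatally to 250 ppm. Against controls, the test found 83% of 100 probe sets shifted by 0.5 log2 and 99% of 100 shifted by 1.0 log2, with 7 false calls (3.7% of calls). The spread was estimated over all 10 groups, so these rates do not describe fits of the compared groups only. The camera test there found the 1 list that was shifted and also called 1 other list. The simulated noise was normal and independent between probe sets, without effects common to an array, so these rates need not hold for the real arrays. Other settings fixed in advance were a filter that left out the dimmest 40% of probe sets, a further quantile normalization, fits of the compared groups only, array weights and leaving out each array. Others were chosen after seeing the data and are named as such with their values. Exact permutation tests of list means were added after seeing the data too. Figures were drawn with matplotlib 3.10.9. Positions in the genome entered only a test of whether called genes are neighbours. The number of arrays limited the precision, and nothing in the labels said that animals of a group came from separate litters.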

Results

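Gene expression in the hippocampus was measured in rats at postnatal day 55 after lead exposure during development, to ask whether the dose, the developmental window and the sex of the animal changed the response. Each of 40 arrays held 1 RNA sample, and the labels gave 10 groups of 4 arrays. Male and female controls were compared with males and females that had 250 or 750 ppm lead in the chow during 1 of 2 windows. Perinatal exposure ran through the dams' chow from 10 days before breeding until weaning, and postnatal exposure ran from birth until postnatal day 45. The arrays gave log2 signals for 29214 probe sets, of which 15310 carried 1 gene symbol. Array medians lay between 6.96 and 7.06, arrays correlated pairwise at r = 0.986 to 0.997 across probe sets, and the median SD within a group was 0.118 log2 (n = 4). The number of arrays limited the precision. Nothing in the labels said that the 4 animals of a group came from separate litters, so p-values measured only the spread between these samples.

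The sex labels of some control arrays did not match their sex-linked transcripts. Eif2s3, an X-linked translation initiation factor subunit, was higher in all 16 exposed female arrays (11.62 to 11.77) than in all 16 exposed male arrays (11.15 to 11.42), and the unnamed probe set 10936669 separated them as well. Among the 8 controls, the array labelled male replicate 4 read 11.69 for Eif2s3, in the female range, and the arrays labelled female replicates 1 and 3 read 11.28 and 11.30, in the male range. The labels were kept, every comparison with controls is therefore one with "the arrays labelled male control" or "female control", and each such count is also given without these 3 arrays. In addition, 3 arrays (male 250 ppm perinatal replicates 1 and 3, male 750 ppm perinatal replicate 1) had flattened signal, with dim probe sets brighter and bright probe sets dimmer than on the other arrays. Their slopes against the mean of all arrays, minus 1, were -0.0191, -0.0314 and -0.0325, and the lowest slope minus 1 among the other arrays was -0.0132. Sample numbers in the titles fell into 3 ranges, with both control groups and the females exposed perinatally to 750 ppm in the lowest. The other 7 exposed groups lay in the other ranges, so for them the range and the exposure cannot be told apart.

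**Figure D1:**
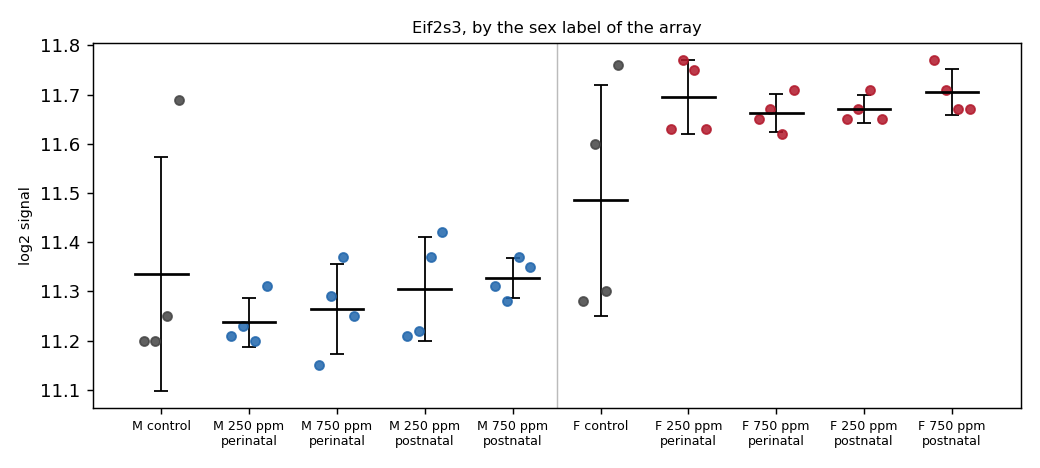
Log2 signal of Eif2s3 on each array (points), with the group mean (line) and SD (bar), n = 4 per group; dark grey marks controls, blue exposed males and red exposed females, by label. The 16 exposed male arrays sit between 11.15 and 11.42 and the 16 exposed female arrays between 11.62 and 11.77, while 1 array labelled male control (11.69) and 2 labelled female control (11.28 and 11.30) lie on the other side.

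In males exposed perinatally to 250 ppm, Ldaf1, a lipid droplet assembly factor, rose and the Fc receptor-like gene Fcrl2 fell, and the genes of myelin rose together while genes induced by neuronal activity fell together. Ldaf1 (probe set 10940603) was 9.21 ± 0.18 against 8.14 ± 0.19 in controls (mean ± SD, n = 4 each), a difference of 1.07 log2 (SE 0.13, adjusted p = 1.94e-05). Fcrl2 differed by -1.26 (SE 0.20, adjusted p = 0.00254) and Bmp3, a bone morphogenetic protein, by -0.95 (SE 0.16, adjusted p = 0.003). Other called genes that were higher were Tmem63a, an ion channel of cell membranes (0.66), Polq, a DNA polymerase (0.48), Lims2 (0.47) and Lyrm1 (0.42). So were the myelin claudin Cldn11 (0.33) and the choline transporter Slc44a1 (0.26). Those that were lower included the RNA polymerase subunits Polr3k (-0.59) and Polr2f (-0.23) and Tnfrsf11b, a decoy receptor of the TNF family (-0.44). All 13 measured oligodendrocyte and myelin markers lay above controls, with a mean difference of 0.27 log2. Cldn11 alone passed over all probe sets and 9 passed adjusted over the list alone. The list passed the camera test (adjusted p = 1.38e-16, and adjusted p = 0.0439 with an estimated correlation), as did oligodendrocyte precursor markers (mean 0.16, 5 of 5 higher, adjusted p = 0.000451, estimated correlation adjusted p = 0.0439). All 20 activity-induced genes lay below controls (mean -0.31, adjusted p = 2.66e-16, and adjusted p = 0.0439 with an estimated correlation). Of these, 12 passed adjusted over the list alone and 0 over all probe sets, among them Nr4a1 (-0.61, SE 0.17), Junb (-0.49, SE 0.13) and the synaptic plasticity gene Arc (-0.47, SE 0.13). Heat shock and ER stress genes were lower in 16 of 18 (mean -0.14, adjusted p = 3.17e-07), and this call was lost with an estimated correlation (adjusted p = 0.0814). Smaller shifts of microglia markers (mean -0.08, estimated correlation adjusted p = 0.281), striatum markers (-0.12, estimated correlation adjusted p = 0.0572), interneuron markers (-0.06) and GABA signalling genes (-0.05), and of astrocyte markers (0.05), also passed with the preset correlation; for the last 3 the adjusted p was 0.404 with an estimated correlation. In all, 26 probe sets passed the limma test (17 higher, 9 lower). This count was 13 without the 3 mismatched controls and 5 without the 3 flattened arrays, and leaving out single arrays gave 9 (without exposed replicate 1) to 20.

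In males exposed perinatally to 750 ppm, Ldaf1 was again higher, Fbln2 and Cd93 were lower, and so were the activity-induced and heat shock lists. Ldaf1 differed by 0.64 log2 (SE 0.13, adjusted p = 0.0285), and Gldn (gliomedin, 0.50, SE 0.09), Tfcp2l1 (0.37) and Plekhg5 (0.31) were higher too. Fbln2, an extracellular matrix fibulin, differed by -1.04 (SE 0.17, adjusted p = 0.00684), the endothelial receptor Cd93 by -0.57 (SE 0.11). Id1, a transcription inhibitor, differed by -0.38, Zfp36l1, an mRNA decay factor, by -0.37 and Tmem176b by -0.37. Mx2, an interferon-induced gene, differed by -1.87 (SE 0.35, adjusted p = 0.0157), with values that overlapped those of controls. Activity-induced genes were lower in 19 of 20 (mean -0.35, adjusted p = 1.21e-13, and adjusted p = 0.0497 with an estimated correlation), with Arc at -0.58 (SE 0.13) and Fos at -0.88 (SE 0.21); 11 passed adjusted over the list alone. Heat shock and ER stress genes were lower in 17 of 18 (mean -0.20, adjusted p = 1.84e-13, and adjusted p = 0.0268 with an estimated correlation), with the chaperones Pdia6 at -0.31 and Hspa5 at -0.26 and 6 genes past the threshold adjusted over the list alone. Myelin markers averaged 0.08 above controls (adjusted p = 0.0376, and adjusted p = 0.609 with an estimated correlation) and oligodendrocyte precursor markers 0.11 (adjusted p = 0.0498, and adjusted p = 0.371 with an estimated correlation). Endothelial and mural cell markers averaged -0.13, immune and interferon genes -0.18 and choroid plexus and ependyma markers -0.83, and all 3 calls were lost with an estimated correlation (adjusted p = 0.371, 0.356 and 0.609). The calls of 5 other lists were lost with an estimated correlation (adjusted p = 0.356 to 0.537), at means of -0.06 (microglia), -0.18 (thalamus and habenula), 0.03 (postsynaptic density), 0.04 (synaptic vesicle release) and 0.02 (calcium signalling). The limma test called 17 probe sets (6 higher, 11 lower), 5 without the 3 mismatched controls and 0 without the 3 flattened arrays. Leaving out single arrays gave 4 (without exposed replicate 1) to 22 (without exposed replicate 3).

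Postnatal exposure of males gave higher Ldaf1 and Pyroxd2, an oxidoreductase, at both doses. At 250 ppm, Ldaf1 differed by 0.83 log2 (SE 0.13, adjusted p = 0.00284), Pyroxd2 by 0.75 (SE 0.15, adjusted p = 0.046) and the receptor gene Gpr63 by 0.26 (SE 0.05, adjusted p = 0.046). At 750 ppm, Ldaf1 differed by 0.99 (SE 0.13, adjusted p = 9.22e-05), Pyroxd2 by 0.89 (SE 0.15), Chchd5 by 0.56 and Lyrm1 by 0.40. Lower at 750 ppm were Fcrl2 (-1.53, SE 0.20, adjusted p = 9.22e-05), the vomeronasal receptor gene Vom2r44 (-0.90), Crabp1, a retinoic acid binding protein (-0.80), and the vesicular monoamine transporter Slc18a1 (-0.48). All 13 myelin markers were higher at both doses (means 0.18 and 0.22, adjusted p = 5.54e-09 and 2.93e-10), and both calls were lost with an estimated correlation (adjusted p = 0.267 and 0.137). Activity-induced genes averaged -0.32 at 250 ppm (18 of 20 lower, adjusted p = 1.3e-15, and adjusted p = 0.0547 with an estimated correlation) and -0.28 at 750 ppm (19 of 20 lower, adjusted p = 1.27e-09, and adjusted p = 0.123 with an estimated correlation), with Nr4a3 at -0.34 (SE 0.08) and -0.31 (SE 0.08). Precursor markers averaged 0.14 and 0.15 (estimated correlation adjusted p = 0.0634 and 0.0911), and heat shock and ER stress genes -0.13 and -0.10 (estimated correlation adjusted p = 0.235 and 0.432). At 750 ppm all 5 red blood cell genes were higher (mean 0.63, adjusted p = 3.18e-08, and adjusted p = 0.0785 with an estimated correlation) and all 5 passed adjusted over the list alone, with Alas2, the erythroid enzyme of heme synthesis, at 0.80 (SE 0.17) and the globin Hbb-b1 at 0.70 (SE 0.20). Heme synthesis genes averaged 0.15, ribosomal proteins 0.06, oxidative stress defence 0.06, oxidative phosphorylation 0.04 and hypothalamic and pituitary hormones -0.11, and these calls were lost with an estimated correlation (adjusted p = 0.392, 0.123, 0.408, 0.566 and 0.408). At 250 ppm 10 probe sets passed (8 higher, 2 lower), 5 without the 3 mismatched controls and 0 without exposed replicate 3. At 750 ppm 13 passed (8 higher, 5 lower), 17 without the mismatched controls, and 8 (without control replicate 2) to 17 with single arrays left out.

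**Figure D2:**
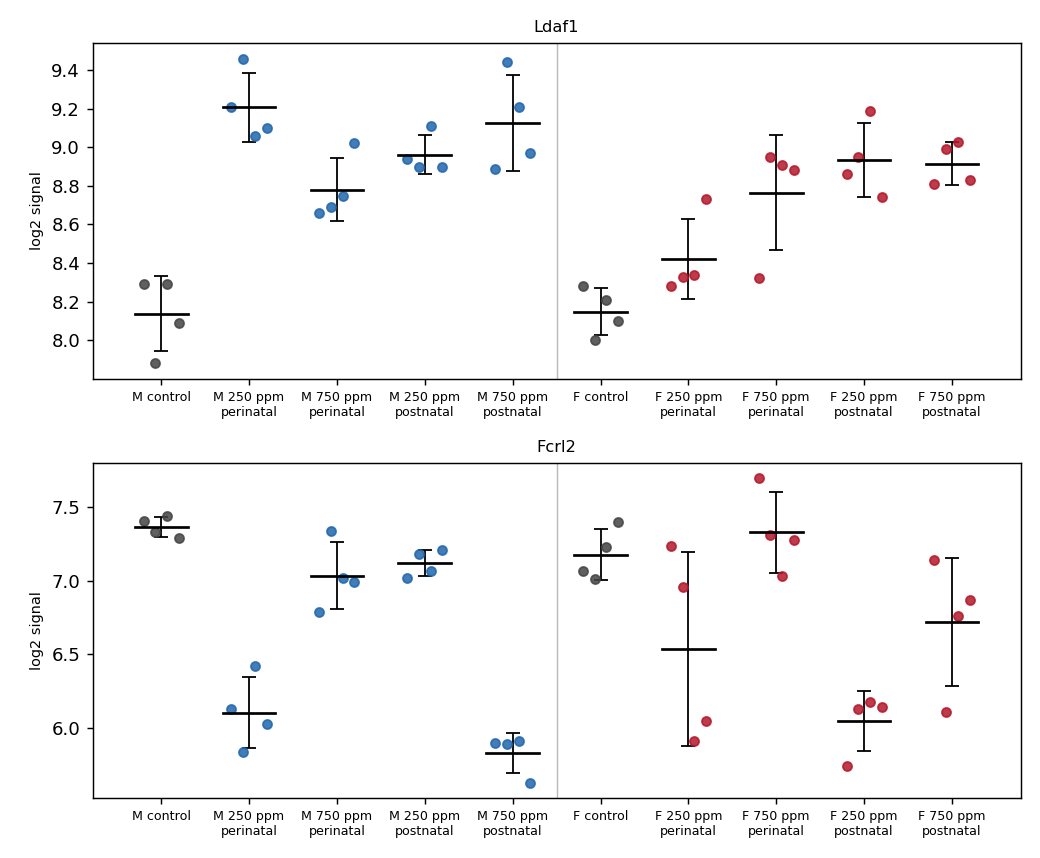
Log2 signal of Ldaf1 (top) and Fcrl2 (bottom) on each array (points), with the group mean (line) and SD (bar), n = 4 per group; dark grey marks controls, blue exposed males and red exposed females. Ldaf1 averaged 8.14 and 8.15 in the control groups and 8.42 to 9.21 in the exposed groups, and Fcrl2 averaged 5.83 to 7.33 in the exposed groups with values of 5.91 to 7.24 within the females exposed perinatally to 250 ppm.

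Females exposed perinatally to 250 ppm differed from controls in few single genes. Eefsec, a translation elongation factor for selenoproteins, differed by -0.31 log2 (9.40 ± 0.13 against 9.71 ± 0.08, mean ± SD, n = 4 each, SE 0.06, adjusted p = 0.0402) and was the only named gene called. All 13 myelin markers were higher (mean 0.27, adjusted p = 6.3e-20), 11 of them past the threshold adjusted over the list alone, with Ugt8, an enzyme of myelin lipid synthesis, at 0.48 (SE 0.11) and Cnp at 0.25 (SE 0.06); the list's adjusted p was 0.0598 with an estimated correlation. Precursor markers averaged 0.13 (estimated correlation adjusted p = 0.102), calcium signalling 0.04 (0.102 likewise), heat shock and ER stress genes -0.09 (0.542), interneuron markers -0.06 (0.542), red blood cell genes -0.27 (0.55) and choroid plexus and ependyma markers -1.23 (0.832), all past the threshold with the preset correlation only. The count was 5 probe sets (2 higher, 3 lower), 9 without the 3 mismatched controls, of which 1 was among the 5, and 1 without control replicate 1.

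Females exposed perinatally to 750 ppm had higher transcripts of Alb and Apoc3, which the liver expresses strongly, of the glucocorticoid-induced gene Tsc22d3 and of the enzymes Gpd1 and Sult1a1. Albumin (Alb) was 7.12 ± 0.49 against 6.09 ± 0.17 in controls (mean ± SD, n = 4 each), a difference of 1.04 log2 (SE 0.14, adjusted p = 9.27e-05), and the apolipoprotein Apoc3 differed by 0.80 (SE 0.13, adjusted p = 0.00191). Of 11 probe sets shared by several major urinary protein (Mup) genes, 8 were called, by up to 1.77 log2 (probe set 10877286, SE 0.19, adjusted p = 5.99e-07). The glycerol phosphate dehydrogenase Gpd1 differed by 1.04 (SE 0.20), the sulfotransferase Sult1a1 by 0.83 (SE 0.16). The thiamine transporter Slc19a3 was 8.41 ± 0.25 against 7.41 ± 0.07 (SE of the difference 0.19, adjusted p = 0.00946). Hif3a, of the hypoxia-inducible factor family, differed by 0.75 (SE 0.15), Fam83d by 0.64 (SE 0.11) and Ldaf1 by 0.62 (SE 0.13, adjusted p = 0.0254). Tsc22d3, induced by glucocorticoids, differed by 0.57 (SE 0.11, adjusted p = 0.00946), beside Fkbp5 at 0.43 (SE 0.10, adjusted p = 0.0851) and Sgk1 at 0.42 (SE 0.15, adjusted p = 0.547), which did not pass. The list of 11 glucocorticoid and sex steroid signalling genes did not pass either (mean 0.11, 6 higher and 5 lower, adjusted p = 0.343), and the receptor gene Nr3c2 was among the lower ones (-0.18, adjusted p = 0.427). The astrocyte connexin Gjb6 differed by 0.42 (SE 0.09, adjusted p = 0.0475). Oligodendrocyte precursor markers were higher in 5 of 5 (mean 0.18, adjusted p = 0.00013, and adjusted p = 0.0364 with an estimated correlation). Myelin markers averaged 0.16, circadian clock genes 0.11, astrocyte markers 0.08 and metallothioneins and metal transport genes 0.09, with an adjusted p = 0.482 for each with an estimated correlation. Meningeal fibroblast markers averaged 0.33, activity-induced genes -0.12 and choroid plexus and ependyma markers -0.67, with an adjusted p = 0.59 for each with an estimated correlation. The test called 46 probe sets (43 higher, 3 lower), 6 without the 3 mismatched controls (all 6 among the 46), 24 without liver marker and Mup probe sets, and 17 without exposed replicate 4.

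**Figure D3:**
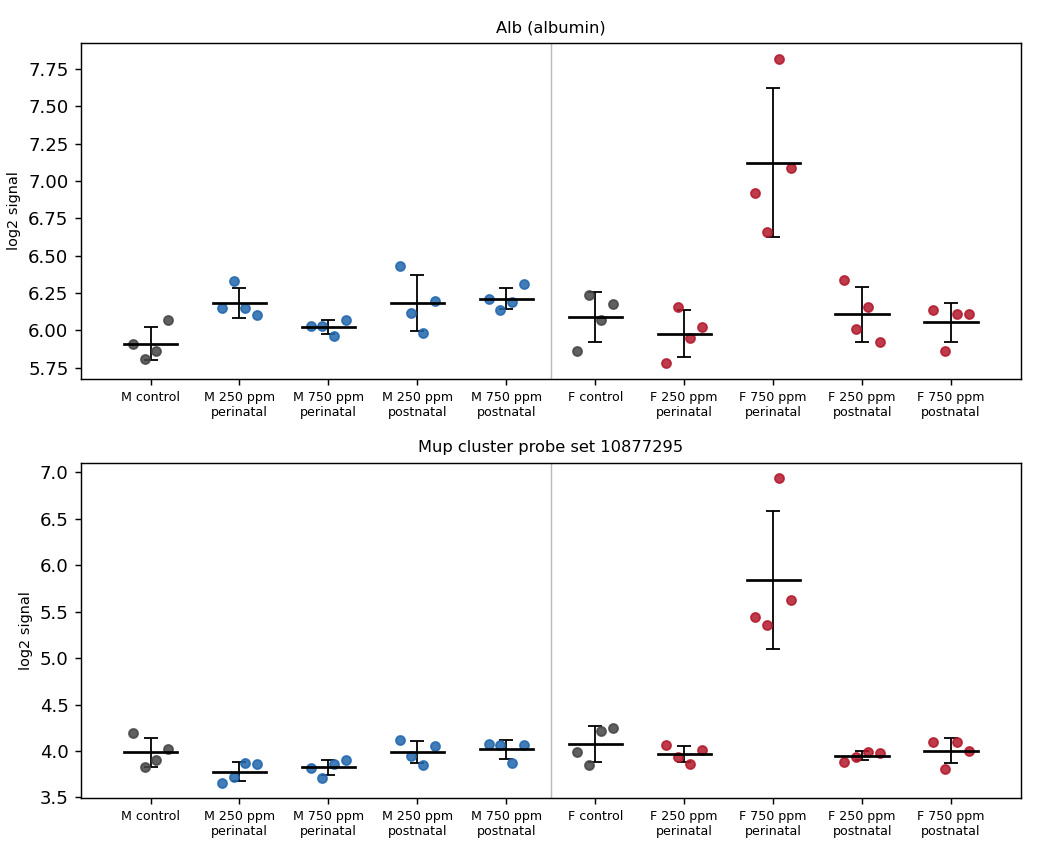
Log2 signal of Alb (top) and of 1 Mup cluster probe set (bottom) on each array (points), with the group mean (line) and SD (bar), n = 4 per group; dark grey marks controls, blue exposed males and red exposed females. In the females exposed perinatally to 750 ppm the arrays read 6.66 to 7.82 for Alb and 5.36 to 6.94 for the Mup probe set.

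Postnatally exposed females differed from controls in few single genes, Ldaf1 among them at both doses. At 250 ppm it was higher by 0.79 log2 (SE 0.13, adjusted p = 0.00625), together with Rab7b, a GTPase of endosome traffic (0.57, SE 0.10, adjusted p = 0.0126), while Fcrl2 was lower (-1.13, SE 0.20, adjusted p = 0.0152). At 750 ppm Ldaf1 was higher by 0.77 (SE 0.13, adjusted p = 0.00691) and no other named gene was called. At 250 ppm all 13 myelin markers were higher (mean 0.20, adjusted p = 1.09e-13), 7 of them past the threshold adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.136). There precursor markers (mean 0.12, estimated correlation adjusted p = 0.136), red blood cell genes (-0.25, 0.553 likewise), interneuron markers (-0.06, 0.553) and heat shock and ER stress genes (-0.04, 0.788) passed with the preset correlation only, as did 3 sex chromosome genes (0.12, 0.37), the list that the mismatched controls bear on directly. At 750 ppm meningeal fibroblast (0.45), endothelial and mural (0.12), microglia (0.06) and precursor markers (0.10) and metal transport genes (0.07) were higher. Activity-induced (-0.14), red blood cell (-0.23) and heat shock and ER stress genes (-0.05) were lower, and each of these 8 lists had an adjusted p = 0.52 with an estimated correlation. The counts were 5 probe sets at 250 ppm (3 higher, 2 lower; 4 without the mismatched controls; 2 without exposed replicate 2) and 4 at 750 ppm (4 higher; 6 without the mismatched controls; 2 without exposed replicate 3).

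**Figure D4:**
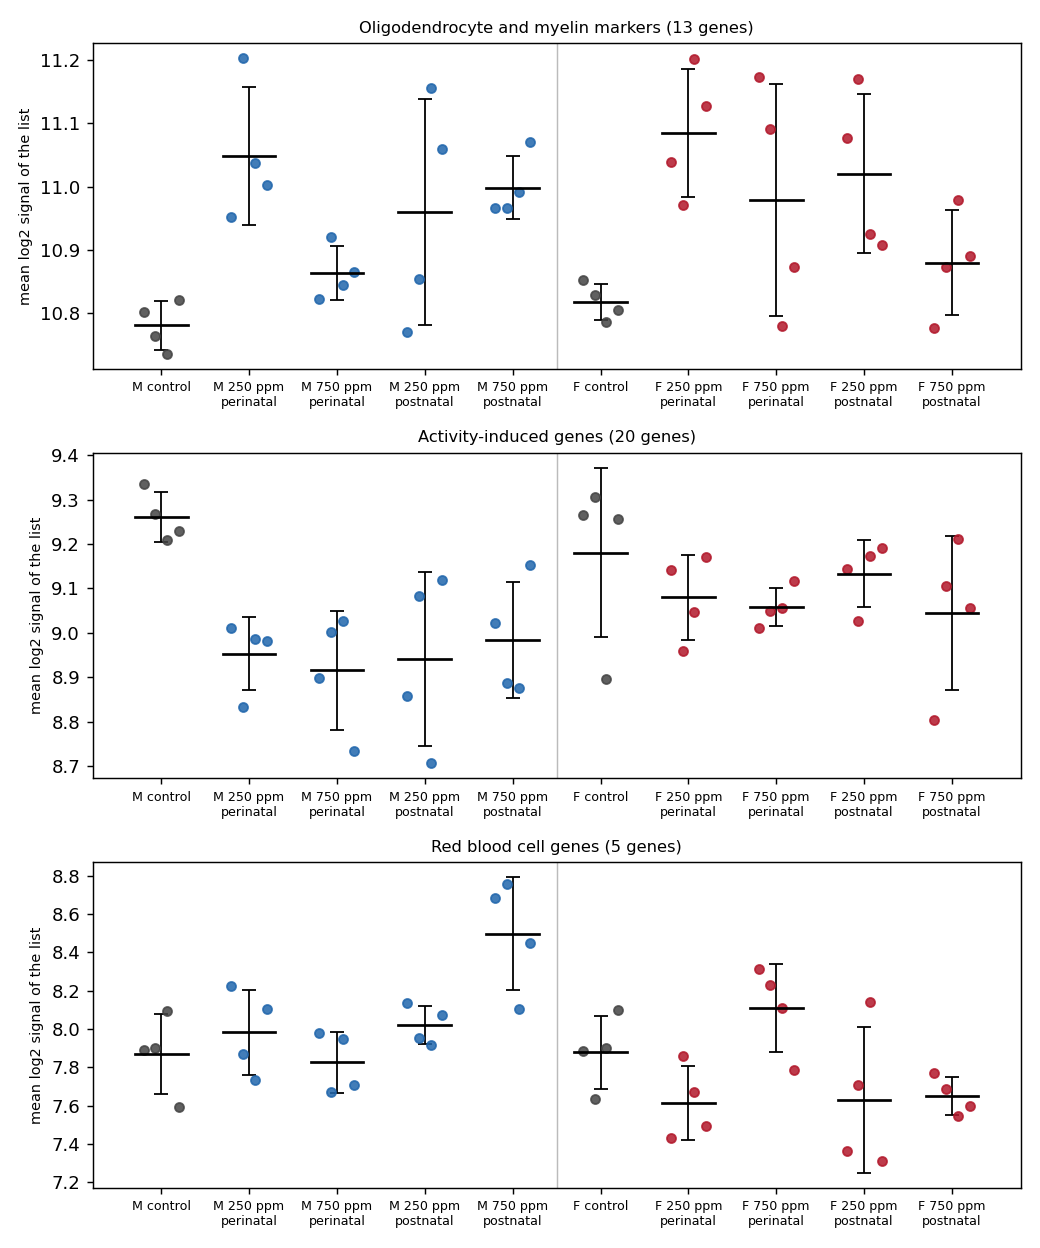
Mean log2 signal over the genes of 3 lists on each array (points): oligodendrocyte and myelin markers (top), activity-induced genes (middle) and red blood cell genes (bottom), with the group mean (line) and SD (bar), n = 4 per group; dark grey marks controls, blue exposed males and red exposed females. Against controls of the same label, myelin markers averaged 0.08 to 0.27 higher in 7 exposed groups. They averaged 0.06 higher in females at 750 ppm postnatally (camera test at the preset correlation, adjusted p = 0.0668, not past the threshold). Activity-induced genes averaged -0.28 to -0.35 in the 4 exposed male groups. With an estimated correlation, the myelin call held only in males at the lower dose perinatally. The activity-induced calls of males then held only after perinatal exposure, at both doses.

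Between doses, the 2 perinatal comparisons also cross title number ranges, so that dose and range cannot be told apart there. The postnatal ones lie within 1 range, but each group has its own run of sample numbers. A difference that goes with these numbers could not be told apart from dose there either. In males exposed perinatally, 750 ppm gave higher Commd6 (0.68 log2, SE 0.14), Epm2a, the glycogen phosphatase laforin (0.61, SE 0.12), and Gldn (0.48, SE 0.09) than 250 ppm. It gave lower Fbln2 (-0.95, SE 0.17), Txnip, a thioredoxin inhibitor (-0.91, SE 0.15), and Tmem63a (-0.82, SE 0.13). Their 13 myelin markers were all lower at 750 ppm (mean -0.18, adjusted p = 7.81e-10, and adjusted p = 0.579 with an estimated correlation). In females exposed perinatally, 750 ppm gave higher Alb (1.15, SE 0.14), Sult1a1 (0.86), Apoc3 (0.76), Tsc22d3 (0.51, adjusted p = 0.0417) and the metallothioneins Mt1 (0.41, SE 0.09, adjusted p = 0.0428) and Mt2A (0.36, SE 0.07, adjusted p = 0.0278). It gave lower carbonic anhydrase Car4 (-0.38) and Phf20l1 (-0.30). Calcium signalling genes were lower in 20 of 25 (mean -0.05, adjusted p = 4.82e-06, and adjusted p = 0.0172 with an estimated correlation), with the kinase Camk2a at -0.08 (SE 0.03). Red blood cell genes were higher (mean 0.50, adjusted p = 0.000121, and adjusted p = 0.284 with an estimated correlation). After postnatal exposure, males at 750 ppm had lower Fcrl2 (-1.29), Vom2r44 (-0.77) and Slc18a1 (-0.48) than at 250 ppm. They had higher red blood cell genes (mean 0.48, adjusted p = 7.67e-08, and adjusted p = 0.0745 with an estimated correlation). In females no probe set passed (smallest adjusted p = 0.0926). Among named genes the smallest p-values belonged to Rab7b (-0.50, SE 0.10, adjusted p = 0.137), Tnik (0.45) and Tigar (-0.35). There 1068 probe sets (3.66%) had an unadjusted p under 0.05, fewer than chance alone gives on average. Meningeal fibroblast markers, which come from the membrane around the brain, were higher at 750 ppm in females (means 0.45 perinatally and 0.55 postnatally) and lower in males perinatally (-0.34), calls lost with an estimated correlation (adjusted p = 0.551, 0.607 and 0.618). The counts were 12 (males, perinatal; 1 without the flattened arrays, and 3 without the 250 ppm replicate 3), 3 (males, postnatal; 0 without the 250 ppm replicate 2), 25 (females, perinatal; 2 without liver marker and Mup probe sets, and 8 without the 750 ppm replicate 3) and 0 (females, postnatal).

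Between windows, the 2 comparisons at 750 ppm also cross title number ranges, so that window and range cannot be told apart there. Those at 250 ppm lie within 1 range, though each group has its own run of sample numbers. In males at 750 ppm, postnatal exposure gave higher Txnip (0.98 log2, SE 0.15, adjusted p = 0.00122), Alas2 (0.94, SE 0.17), C18h5orf63 (0.75) and the microglial receptor Csf1r (0.22, SE 0.05, adjusted p = 0.0496). It gave lower Fcrl2 (-1.20), Vom2r44 (-0.76) and Sprn, a prion-like protein gene (-0.61). All 5 red blood cell genes (mean 0.67, estimated correlation adjusted p = 0.18), 14 of 15 microglia markers (0.12, 0.294 likewise), 23 of 25 ribosomal proteins (0.08, 0.18) and all 13 myelin markers (0.14, 0.682) were higher, past the threshold with the preset correlation only. In females at 750 ppm, postnatal exposure gave lower Nat8f1, an N-acetyltransferase family member (-1.17 log2, SE 0.13, adjusted p = 8.43e-07), Alb (-1.07, SE 0.14), Apoc3 (-0.75) and Tsc22d3 (-0.60, SE 0.11, adjusted p = 0.0069). Their 5 red blood cell genes were all lower (mean -0.46, adjusted p = 2.34e-05, and adjusted p = 0.191 with an estimated correlation). Their circadian clock genes were lower in 12 of 14 (mean -0.13, adjusted p = 4.03e-06, and adjusted p = 0.191 with an estimated correlation), with Per1 at -0.41 (SE 0.09, adjusted p = 0.0898). At 250 ppm the windows differed in Ldah, a lipid droplet hydrolase, in males (0.75, SE 0.11, adjusted p = 0.00291, with overlapping values because 1 perinatal array read 9.52 and the lowest 8.62). In females they differed in Slc29a4, a monoamine transporter (0.53, SE 0.10), and the kinase Tnik (-0.55, SE 0.10, adjusted p = 0.0235). Choroid plexus and ependyma markers were higher after postnatal exposure in males at 250 ppm (mean 1.19) and 750 ppm (1.15) and females at 750 ppm (0.75), calls lost with an estimated correlation (adjusted p = 0.764, 0.682 and 0.741). In females at 250 ppm the mean was 1.03 and did not pass (adjusted p = 0.0716). Single arrays spread widely within groups, for example from 6.89 to 9.71 in males at 750 ppm postnatally. The windows overlapped in each of these comparisons. The counts were 51 (males, 750 ppm; 33 higher, 18 lower), 16 (females, 750 ppm; 2 higher, 14 lower), 1 (males, 250 ppm) and 3 (females, 250 ppm). Leaving out single arrays gave 0 (without perinatal replicate 3) to 2 in males at 250 ppm and 0 (without perinatal replicate 2) to 9 in females at 250 ppm. In females at 750 ppm it gave 12 to 20. In males at 750 ppm the count was 14 without the flattened arrays, all among the 51, and 15 (without perinatal replicate 1) to 327 (without perinatal replicate 2) with single arrays left out.

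The control groups did not differ by sex label in any probe set. With 3 of the 8 control arrays on the side of the other sex, this cannot show whether the sexes differed. The limma test gave a smallest adjusted p = 0.994. An unadjusted p under 0.05 was found for 1352 probe sets (4.63%), fewer than chance alone gives on average. The named genes of smallest p were Id1 (-0.30 log2, female minus male, SE 0.08), Or2r11 (-0.41) and Esco1 (0.38). Without the 3 mismatched arrays 4 probe sets passed. In the arrays labelled female against those labelled male, all 8 included, glutamate receptor genes averaged 0.04 and endothelial markers -0.09. Both had an adjusted p = 0.0455 by the camera test and, with an estimated correlation, an adjusted p = 0.662. The difference from controls differed by sex, as an interaction of female minus male differences, in 6 probe sets for 750 ppm perinatally. For each of the other 3 exposures 0 passed. There 979 (3.35%), 671 (2.3%) and 1241 (4.25%) probe sets had an unadjusted p under 0.05, fewer than chance alone gives on average. The named genes were Nat8f1 (1.14 log2, SE 0.18, adjusted p = 0.00399) and Id1 (0.60, SE 0.11, adjusted p = 0.0095), and the other 4 probe sets belonged to the Mup cluster (0.99 to 1.98). Liver RNA in the samples may account for the Mup values. The value of Id1 rests in part on the control groups, whose difference of -0.30 did not pass. Only 2 of the 6 passed without the 3 mismatched controls. For this exposure the females lay in the title number range of the controls and the males in another, so that sex and range cannot be told apart. In the other 3 exposures the exposed groups of both sexes lay in the same range, though each had its own run of sample numbers. Red blood cell genes had a mean interaction of -0.86 after 750 ppm postnatally, with 5 of 5 negative. The camera test gave an adjusted p = 4.57e-12, and 0.00853 with an estimated correlation. Means against controls were 0.63 in males and -0.23 in females. This interaction rests on all 8 control arrays, 3 of them mismatched, and its cause was not tested. Activity-induced genes had positive mean interactions in all 4 exposures (0.14 to 0.27), past the threshold with the preset correlation and lost with an estimated one (adjusted p = 0.472 to 0.754). All 4 rest on the same 8 control arrays. Without the 3 mismatched controls the preset test kept those at 250 ppm (adjusted p = 0.00822 perinatally and 0.00403 postnatally) and lost those at 750 ppm (0.0724 and 0.619).

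Genes with a record in lead toxicology that were tested numbered 14, each represented by its probe set of highest mean, and 0 passed against controls in any of the 8 exposures. The largest difference was that of the metallothionein Mt2A in females at 750 ppm perinatally (0.32 log2, SE 0.07, adjusted p = 0.0682), where its second probe set passed (0.40, SE 0.09, adjusted p = 0.0475). The means over the 14 genes lay between -0.01 and 0.06. Differences from controls correlated between exposures of the same sex at r = 0.20 to 0.63 across probe sets (mean 0.41 over 12 pairs), where genes are not independent replicates. Shared control arrays alone gave a mean r = 0.48 in 100 simulations of unchanged groups, and the mean covariance was 0.00609 against a simulated 0.0067. With the controls split between the members of a pair, the mean r was -0.05 (-0.17 to 0.09).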

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

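Of the tests below, those of exchanged sex labels, mixed RNA, female liver RNA, title number ranges and neighbouring genes were chosen after the result was seen. Chance puts an array far from the others in about 1 in 20 groups, and this happened in 23 of 369 groups of 4 values of named genes and lists, where chance gives about 18.

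Single arrays stood apart from the other 3 of their group in 15 gene values. These were Alad (8.66, females 750 ppm perinatal replicate 2), Alb (5.86, females 750 ppm postnatal replicate 2), Camk2a (12.96, male control replicate 4), Dnmt1 (9.01, females 750 ppm perinatal replicate 4), Eefsec (9.21, females 250 ppm perinatal replicate 2) and Esco1 (8.51, male control replicate 2). Fcrl2 did so in females at 250 ppm postnatal replicate 1 (5.74) and in males at 750 ppm postnatal replicate 4 (5.63). Gfap (11.39, males 250 ppm perinatal replicate 2), Ldaf1 (8.32, females 750 ppm perinatal replicate 1), and Ldah (9.52) and Nr4a1 (9.23, both males 250 ppm perinatal replicate 1) did so too. Mbp (11.91, male control replicate 3), Sult1a1 (8.26, female control replicate 1) and Ugt8 (10.38, female control replicate 3) were the rest. Among list means, activity-induced genes stood apart in female control replicate 3 (8.90) and males 250 ppm perinatal replicate 2 (8.83). Choroid plexus and ependyma markers did so in females 250 ppm perinatal replicate 3 (9.01), female control replicate 1 (6.62) and males 750 ppm postnatal replicate 3 (6.89). Circadian clock genes (9.55, females 750 ppm postnatal replicate 2), heat shock and ER stress genes (9.31, males 750 ppm postnatal replicate 2) and hypothalamic and pituitary hormones (5.96, male control replicate 4) did so once each.

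The difference from controls differed between the sexes, by a test of the interaction (female minus male difference, log2), in single genes after 750 ppm perinatally. These were Nat8f1 (1.14), Id1 (0.60) and 4 Mup cluster probe sets (1, 0.99, 1.98 and 1.93). For this exposure the females lay in the title number range of the controls and the males in another, so that sex and range cannot be told apart there. Among lists, the interaction after 250 ppm perinatally was 0.21 for activity-induced genes and -0.38 for red blood cell genes. After 750 ppm perinatally it was -0.03 for postsynaptic density, 0.22 for activity-induced, -0.04 for calcium signalling, 0.19 for heat shock and ER stress, and 0.12 for microglia genes. It was 0.22 for endothelial and mural, 0.48 for meningeal fibroblast and 0.35 for thalamus and habenula genes. After 250 ppm postnatally it was 0.27 for activity-induced, -0.40 for red blood cell and -0.86 for choroid plexus and ependyma genes. After 750 ppm postnatally it was 0.14 for activity-induced, -0.06 for oxidative stress defence, and -0.86 for red blood cell genes. It was -0.04 for oxidative phosphorylation, -0.05 for ribosomal protein, -0.16 for myelin, 0.15 for immune and interferon and 0.11 for endothelial and mural genes. With an estimated correlation, red blood cell genes after 750 ppm postnatally alone passed among these lists (adjusted p = 0.00853).

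The first pattern is the sex-linked signal of the controls, where 3 of 8 arrays lay on the side of the other sex. Noise of the sex-linked probe sets is argued against, since 0 of 32 exposed arrays fell on the wrong side, and so is mixed RNA of both sexes, since 0 of the 3 arrays lay between the ranges of the sexes. Exchanged sex labels stay open as a candidate explanation, since all 3 arrays lay inside the range of the other sex, with 1 under the male and 2 under the female label. An equal exchange between the groups would need as many arrays from each, so at least 1 array would need another source. No biological explanation was tested.

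The second pattern is the liver transcripts in the females exposed perinatally to 750 ppm. A title number range as the cause is argued against, since Alb exceeded the 8 controls of the same range by 1.12 log2. Liver RNA in the samples may account for it: the median of 26 liver markers other than Alb, Apoc3 and Apoh was 0.16, above 100% of 10000 random lists of like expression. The abundant liver transcripts Apoa1 (-0.04), Apoa2 (-0.02), Hp (0.00) and Fga (-0.01) were not raised, however. Apoa1, Apoa2 and Hp were about as dim in the female controls as Alb, which was raised, so dimness does not set them apart. Whether liver RNA could come from a female animal stays open: male-predominant genes exceeded female-predominant ones by 0.43 log2, but this rests on the Mup cluster, itself part of the pattern, and with its 11 probe sets as 1 value (a change made after the first value was seen) the difference was 0.004. The exposure itself stays open, as do glucocorticoid effects on these genes, which were not tested.

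The third pattern is the 6 genes called in 2 or more exposures (Ldaf1, Fcrl2, Lims2, Lyrm1, Pyroxd2 and Tfcp2l1). The title number range as the whole cause is argued against for Ldaf1, called in 7 exposures. It was called in females exposed perinatally to 750 ppm against controls of the same range (0.62 log2, adjusted p = 0.0254). Lims2 (0.54, 0.00484) and Tfcp2l1 (0.40, 0.00946) were called there too. Each of these was called in 2 exposures and so joined the 6 genes only through this call, which decides nothing for the pattern. The range stays open for all but Ldaf1, while Ldaf1 at 750 minus 250 ppm in perinatally exposed females (0.35, SE 0.13, adjusted p = 0.441, overlapping values) decides nothing. For shared control arrays, Ldaf1 differed among the 8 exposed groups (adjusted p = 0.00653 by an F test). The bound set before for this test was wrong by design. Low control values would shift all 8 groups alike and leave differences among them untouched. Ldaf1, Fcrl2, Lims2 and Tfcp2l1 were each called in both sexes, against separate control arrays, so sharing alone does not account for calls in both sexes. It stays open for repeated calls within 1 sex, which include all those of Lyrm1 and Pyroxd2. Low values in both control groups stay open too. Inherited variants shared by litters were tested by whether called genes are neighbours in the genome, and over all 55 named genes called in an exposure they were not beyond chance (share of random draws 0.464). Among the 6 genes, Lyrm1 and Ldaf1 are neighbours, as in 0.00601 of random draws, but this test was chosen after the pair had been noticed and decides nothing, so that a variant may still account for these genes and cannot be told apart from the exposure, with no litters named in the labels.

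Other splits of the same arrays were counted for each comparison, 35 splits for 2 groups. The labelled grouping called the most probe sets in several comparisons. As 1 of 35 is the smallest share that 35 splits can give, and many comparisons were tried without adjustment, this does not exclude chance. It called the most for males at 750 ppm perinatally (17 called, highest of the other splits 2, as many in 1 of 35 splits). So it did for males at 250 ppm postnatally (10, highest 1, 1 of 35) and 750 ppm postnatally (13, highest 0, 1 of 35). The same holds for females at 250 ppm perinatally (5, highest 2), 750 ppm perinatally (46, highest 15), 250 ppm postnatally (5, highest 1) and 750 ppm postnatally (4, highest 2), each 1 of 35. It also holds for dose in females perinatally (25, highest 3), and for the window in males at 750 ppm (51, highest 7), females at 250 ppm (3, highest 1) and females at 750 ppm (16, highest 0), each 1 of 35. For the interaction at 750 ppm perinatally (6 called) another split called more (highest 9, as many in 2 of 100 splits). Some of these counts still rest on 1 array, since 0 were left without 1 exposed array for males at 250 ppm postnatally and without 1 perinatal array for the window in females at 250 ppm. At least 1 other split also called more for males at 250 ppm perinatally (26, highest 1640, 2 of 35), dose in males perinatally (12, highest 3155, 5 of 35), dose in males postnatally (3, highest 71, 2 of 35) and the window in males at 250 ppm (1, highest 3, 10 of 35). No other outcome was possible where 0 were called, since every split gives at least as many, so the count says nothing about chance there. These were dose in females postnatally (0 by limma with 1068 at an unadjusted p under 0.05, highest 2, 35 of 35), sex in controls (0 with 1352, highest 8, 35 of 35) and the interactions at 250 ppm perinatally (0 with 979, highest 905, 100 of 100), 250 ppm postnatally (0 with 671, highest 6, 100 of 100) and 750 ppm postnatally (0 with 1241, highest 4, 100 of 100). The splits that called 1640 and 3155 probe sets put flattened arrays on one side and, like the split that called 71, parted arrays by their choroid plexus markers (-0.70, -0.88 and 1.13 log2), a structure of the samples apart from the groups.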

How the results depend on the processing

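The alternatives without the mismatched controls, with all 8 controls, with the probe table only, without liver and Mup probe sets and without the flattened arrays were chosen after seeing the data. Over 342 alternative values of counts and summaries, 199 stayed within 1.5 times the value reported and 143 did not. No named gene or list changed direction past the threshold, but many calls of named genes were lost. Without the mismatched controls 31 were lost and 19 held, without the flattened arrays 28 and 10, and with only the compared groups 57 and 24. Array weights lost 21 and kept 60, and a further quantile normalization lost 8 and kept 73. Without the dimmest 40% of probe sets 0 were lost and 74 held. Without the dimmest 40% of probe sets the counts that moved were females 250 ppm perinatal 3, dose in females perinatal 16, window in females 250 ppm 9 and window in females 750 ppm 8. Interaction 750 ppm perinatal 2 moved too. After a further quantile normalization the counts that moved were dose in males postnatal 1 and window in females 250 ppm 9. With only the compared groups in the fit the counts that moved were males 250 ppm perinatal 7, males 750 ppm perinatal 2, males 250 ppm postnatal 0 and males 750 ppm postnatal 7. Females 250 ppm perinatal 1, females 750 ppm perinatal 14, dose in males perinatal 7 and dose in males postnatal 8 moved too. Dose in females perinatal 10, window in males 250 ppm 0, window in males 750 ppm 4 and window in females 250 ppm 6 moved too. Window in females 750 ppm 7 and interaction 750 ppm perinatal 3 moved too. With array weights the counts that moved were males 250 ppm perinatal 10, males 750 ppm perinatal 10, females 250 ppm perinatal 14 and females 750 ppm perinatal 112. Females 250 ppm postnatal 18, females 750 ppm postnatal 8, dose in males perinatal 0 and dose in females perinatal 49 moved too. Dose in females postnatal 9, window in males 250 ppm 0, window in females 250 ppm 24 and window in females 750 ppm 34 moved too. Without the 3 control arrays whose sex-linked probe sets do not match their label the counts that moved were males 250 ppm perinatal 13, males 750 ppm perinatal 5, males 250 ppm postnatal 5 and females 250 ppm perinatal 9. Females 750 ppm perinatal 6, sex in controls 4 and interaction 750 ppm perinatal 2 moved too. With all 8 control arrays as the reference the counts that moved were males 250 ppm perinatal 46, males 750 ppm perinatal 41, males 250 ppm postnatal 16 and females 250 ppm perinatal 59. Females 750 ppm perinatal 114, females 250 ppm postnatal 14 and females 750 ppm postnatal 8 moved too. With probe sets in the probe table only the counts that moved were males 250 ppm perinatal 14, males 250 ppm postnatal 3, females 250 ppm perinatal 0 and females 750 ppm postnatal 1. Dose in males perinatal 20 and interaction 750 ppm perinatal 10 moved too. Without liver marker and Mup probe sets the counts that moved were females 750 ppm perinatal 24, dose in females perinatal 2, window in females 750 ppm 7 and interaction 750 ppm perinatal 2. Without the 3 arrays of flattened signal the counts that moved were males 250 ppm perinatal 5, males 750 ppm perinatal 0, dose in males perinatal 1 and window in males 750 ppm 14. Interaction 250 ppm perinatal 1 moved too. Leaving out single arrays gave males 250 ppm perinatal 9 to 20, males 750 ppm perinatal 4 to 22, males 250 ppm postnatal 0 to 7 and males 750 ppm postnatal 8 to 17. It gave sex in controls 0 to 3, interaction 250 ppm perinatal 0 to 2, interaction 750 ppm perinatal 5 to 13 and interaction 250 ppm postnatal 0 to 0. It gave interaction 750 ppm postnatal 0 to 0, dose in males perinatal 3 to 21, window in males 250 ppm 0 to 2 and window in males 750 ppm 15 to 327. It gave dose in males postnatal 0 to 3, females 250 ppm perinatal 1 to 5, females 750 ppm perinatal 17 to 50 and females 250 ppm postnatal 2 to 5. It gave females 750 ppm postnatal 2 to 7, dose in females perinatal 8 to 26, window in females 250 ppm 0 to 9 and window in females 750 ppm 12 to 20. It gave dose in females postnatal 0 to 1 called probe sets. Fewer arrays or groups leave fewer degrees of freedom, and otherwise the cause was not tested. Of 137 list calls, 8 held with an estimated correlation, 115 without the dimmest 40% of probe sets, 104 without the mismatched controls and 106 without the flattened arrays. With controls split between the exposures of a pair, the mean correlation of 0.41 became -0.05. The title number range as a random block was not run, since each group lies in 1 range and the range adds nothing to the groups (rank 10 with and without it). No paired analysis was possible because the labels carry no replicate numbers shared between groups. Signal near background limits what dim probe sets can show, and 40% of all probe sets had a mean under 6.3.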

Other observations

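The comparison of all exposed with all control arrays, the permutation tests of list means and their settings were chosen after seeing the data. Across the 8 exposed groups (32 arrays) against both control groups (8 arrays), Ldaf1 was higher by 0.75 log2 (SE 0.07, adjusted p = 3.55e-08) and its direction held in 8 of 8 exposed groups. Lyrm1 was higher by 0.28 (SE 0.04), the oxidoreductase Pyroxd2 by 0.58 (SE 0.08), Lims2 by 0.33 and the ATP-gated channel P2rx7 by 0.42, each in 8 of 8 groups. This agreement was nearly fixed in advance, since genes were called on the pooled difference from the same 8 controls. Every called probe set held its direction in 7 or 8 groups. Myelin genes were among the called genes, with Cldn11 at 0.21 (adjusted p = 0.00193), Mog at 0.24, Ugt8 at 0.26 and Olig1 at 0.19, as was the precursor gene Gpr17 at 0.19. Fcrl2 (-0.68), the endothelial receptor Cd93 (-0.33), the zinc transporter Slc39a12 (-0.50) and the serotonin receptor Htr1b (-0.17) were lower. Among activity-induced genes, Nr4a1 (-0.43, adjusted p = 0.0281), Egr2 (-0.40), Junb (-0.32) and Arc (-0.30, adjusted p = 0.0468) were lower, each in 8 of 8 groups. Of the tested genes with a record in lead toxicology, Mt2A alone was called. It was higher by 0.17 (adjusted p = 0.0468), and by 0.23 on its second probe set (adjusted p = 0.032). The limma test called 111 probe sets (88 higher, 23 lower), and 38 without the 3 control arrays whose sex-linked signal did not match their label, 26 of them among the 111.

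As lists, oligodendrocyte and myelin markers were higher in exposed arrays (mean 0.18, adjusted p = 0.0189 with an estimated correlation), as were oligodendrocyte precursor markers (0.14, adjusted p = 0.00279 likewise), while activity-induced genes (-0.21, adjusted p = 0.0189 likewise) and heat shock and ER stress genes (-0.09, adjusted p = 0.0276 likewise) were lower. Two-sided permutation tests of the list means gave p = 0.00028, 1e-05, 0.00039 and 0.00079, in that order, and 1e-05 is the smallest that 1e+05 permutations can give. In males alone (16 arrays against 4, exact permutation tests) activity-induced genes (-0.31), heat shock and ER stress genes (-0.14) and precursor markers (0.14) each gave p = 0.000206, the smallest possible, and myelin markers (0.19) gave p = 0.0066 (0.0594 adjusted). In females alone the exact permutation p was 0.0227 for myelin (0.17), 0.00186 for precursor markers (0.13), 0.152 for activity-induced genes (-0.10) and 0.233 for heat shock and ER stress genes (-0.05), and none of these 4 passed after adjustment over lists. For activity-induced genes, female control replicate 3, a mismatched array, read 8.9 against 9.26 to 9.3 on the other female controls, which makes the female difference smaller. With 4 arrays against 4 the smallest exact p is 0.0286. In a fit with 2 groups, the split into 32 exposed and 8 control arrays called 50 probe sets, 1 of 100 splits gave as many, and the highest of the other splits called 1. Most exposed groups lay in other title number ranges than the controls, so this difference and the range cannot be told apart except for the females exposed perinatally to 750 ppm. In that group precursor markers averaged 0.18 (adjusted p = 0.0364 with an estimated correlation), myelin markers 0.16 (0.482 likewise) and activity-induced genes -0.12 (0.59 likewise). Heat shock and ER stress genes averaged -0.01 there (0.707 likewise), against -0.04 to -0.20 in the 7 other groups, so for this list the group gives no shift apart from the range.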
